A study of Mus musculus with 6 samples.

How the data were processed

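RNA from 6 cultures of mouse cells of strain 129 was measured, each on 1 Affymetrix whole-transcript array. The cultures were epiblast stem cells (EpiSCs, 1 array), patterned neural rosettes at day 5 (1 array), oligodendrocyte progenitor cells (OPCs, 2 arrays) and oligodendrocytes (2 arrays). OPCs and oligodendrocytes were each taken at passage 3, called replicate 1 here, and at passage 11, called replicate 2. Per the labels, total RNA was prepared with a column kit, and biotin-labelled sense-strand target was made from 150 ng of it.

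The deposited values are log2 expression values that the authors made with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects for background, equalises the distributions of the arrays and summarises the probes of each transcript. The software version and the background option are not given in the sources used here. The 6 arrays ranged from 3.26 to 14.9 over all values, with no missing value, and the array medians over all transcripts lay between 8.60 and 8.66 (8.98 to 9.04 over the genes tested). No detection call or signal-over-background value was used, so a low value can be background, and a fold change that involves one can be compressed. The number of arrays limits the precision.

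Of 35556 measured transcripts, 21789 carried exactly 1 gene symbol in the array annotation, 1621 carried several and 12146 had no gene. Gene symbols were compared by Entrez ID with a mouse RefSeq gene table, which held 21698 of the IDs and changed 0 symbols. Where a gene had several measured transcripts (999 genes), the one with the highest mean over the 6 arrays was kept, which left 19938 genes. Transcripts with no symbol or several symbols were left out of the gene tests. Genes without such a transcript in the table used were not analysed here, and some results are not reported here. No genome positions were used.

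Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided). All 6 arrays entered 1 fit with the 4 cell types as groups, which leaves 2 residual degrees of freedom and gave 3.32 prior degrees of freedom. OPCs against the rosette and oligodendrocytes against OPCs were taken from that fit. The spread of the lone rosette array was assumed to equal that pooled within the OPC and oligodendrocyte groups. Passage 11 against passage 3 was tested on the 4 OPC and oligodendrocyte arrays with cell type as a covariate, with 1 residual and 3.19 prior degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The labels do not say whether the cultures of a group were separate beyond their passage, so the p-values measure only the spread between these samples, and in the fit by cell type that spread includes the passage. In the passage fit the 1 residual degree of freedom is the disagreement between the passage differences of OPCs and oligodendrocytes. Its SEs and p-values therefore measure how alike the 2 cell types are, not the spread between cultures of a passage.

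The rosette and the EpiSC array have no replicate, so no p-value was computed for them. Genes were counted by size, with at least 4-fold as the limit. Each gene list was placed by its median among 10000 random lists of the same size, matched on expression over 20 bins. For oligodendrocytes against OPCs, genes at least 2-fold apart in the same direction at both passages were also counted, because that count does not rest on a variance estimate.

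A set of 32 gene lists (pathways, regional identities and cell types) was fixed before the data were examined, as were the tests, the thresholds and the rule for naming genes. Of their 503 entries, 469 were measured. In the 3 tested comparisons each list was tested with camera at its preset correlation of 0.01, again with a correlation estimated from the data, and with fry. Fry values are those of its directional test unless its mixed test is named. The p-values were adjusted over the 32 lists of a comparison. For the members of a list, calls are also given adjusted over the list alone. Among lists that camera called, the median, the mean and the test had the same sign in all 3 comparisons. They differed in sign for 7 uncalled lists in OPCs against the rosette, 5 in oligodendrocytes against OPCs and 3 between passages.

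Named genes are the 12 largest increases and 12 largest decreases among called genes that moved the same way at both passages (in both cell types for passage). Where fewer passed, genes at least 2-fold apart in both filled the places. For the rosette against EpiSCs they are the 12 largest differences each way among genes whose brighter array was above the median of all values, 9.00. Added to these were 24 genes fixed by name, of which 23 were measured, and up to 4 members of each list with the largest differences and a brighter side above that median. Predicted and unnamed genes were passed over in the ranking. Dusp4, Ccnd1, Cyp26a1, Lhx1, Slc1a3, Vegfa, Pfkl, Msi1, Tfap2b and the collagen and proteoglycan genes lie outside this rule in at least 1 place where they are named, and were chosen there after their values were seen.

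The procedure was tested on simulated data with 19938 genes, in 3 runs with 200 genes changed in each run, divided over 3 sizes of change. For oligodendrocytes against OPCs, limma called 6.5% of the genes changed by 1 on the log2 scale, 86.6% of those changed by 2 and 98.0% of those changed by 4, with 15 false calls over the 3 runs. For OPCs against the rosette it called 0.5%, 68.2% and 96.0%, with 23 false calls. For passage it called 1.5%, 81.6% and 96.5%, with 22 false calls. A list shifted as a whole by 1 was called by camera at the preset correlation in 3 of 3 runs of each comparison and at an estimated correlation in 0 of 3. None of the 93 unshifted lists tested in each comparison was called. The simulated genes were drawn independently, with equal spread in all groups and the variance prior of the fit by cell type. On the real arrays the estimated correlation was 0.817 for cell cycle genes in that fit. The passage difference had an SD over genes of 0.461 in oligodendrocytes and 0.264 in OPCs. The simulated false calls therefore do not carry over to correlated lists or unequal spread. In the placement among random lists, a shifted list reached percentile 100 and unshifted lists lay between 22.0 and 46.3.

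The alternatives were a second quantile normalization, centring of each array on its median, removal of dim genes (11880 genes left), all transcripts of the table, variance trends, other thresholds, the mean of a gene's transcripts, passage as a block, and each replicate left out in turn. The block pairs OPCs and oligodendrocytes by the passage given in the labels. The labels do not say whether the oligodendrocytes came from the OPC culture that was measured. The passage difference in OPCs and that in oligodendrocytes correlated across genes with r = 0.503, where genes are not independent replicates. A passage effect shared by the cell types would give this without such a link, so the correlation cannot check the pairing. Removal of an intensity trend between passages (loess, span 0.3) was added after the data had been seen. Groups of at most 2 arrays allow no outlier test and no test of other splits of the samples. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.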

Results

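Gene expression was measured on 6 arrays that follow mouse EpiSCs, pluripotent cells of the postimplantation epiblast, through neural rosettes and OPCs to oligodendrocytes. EpiSCs were grown with knockout serum replacement and FGF2. Rosettes were made in 5 days with the inhibitors SB431542, Dorsomorphin and Noggin, followed by retinoic acid and sonic hedgehog (SHH). OPCs were grown with FGF2, PDGF-AA and SHH, and oligodendrocytes were obtained by adding thyroid hormone and removing FGF2 and PDGF-AA. There was 1 EpiSC array, 1 rosette array, and 2 arrays each of OPCs and oligodendrocytes, at passages 3 and 11. Values are log2 and differences are log2 differences, given with the standard error (SE) of the limma fit where groups have replicates.

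The first principal component held 46.4% of the variance and ordered the arrays by stage, from EpiSCs at -69.1 through the rosette at -29.1 and OPCs at 10.0 and 16.6 to oligodendrocytes at 29.9 and 41.8. Across genes, which are not independent replicates, the OPC arrays of the 2 passages correlated at 0.990 and the oligodendrocyte arrays at 0.968. The EpiSC and rosette arrays correlated at 0.926.

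**Figure D1:**
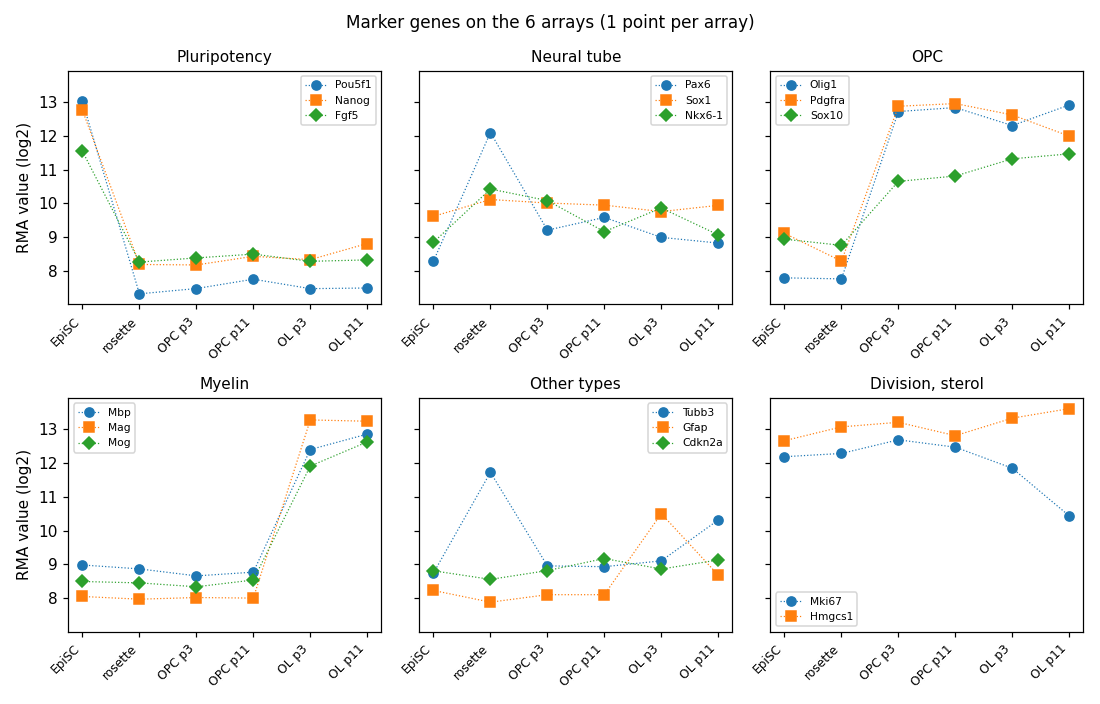
Expression of stage markers on each of the 6 arrays (RMA value, log2, 1 point per array; OL, oligodendrocyte; p, passage; dotted lines only join the points of a gene). Pou5f1 stands at 13.02 in EpiSCs and 7.33 in the rosette, and Mag and Mbp stand highest on the oligodendrocyte arrays.

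The first comparison asked how day 5 rosettes differ from the EpiSCs they came from. Most pluripotency genes were lower in the rosette (12 of 16 at least 2-fold): Tdgf1, the Nodal co-receptor Cripto, by -6.23 (74.9-fold), the transcription factor Pou5f1 by -5.69 (13.02 to 7.33), Utf1 by -5.30 and Nanog by -4.56. Most neuronal genes of the fixed list were higher (14 of 18 at least 2-fold), led by Dcx, which encodes a microtubule protein, at 4.86 (7.79 to 12.66). Of 15 neuroepithelial genes 9 were at least 2-fold higher, led by the transcription factor gene Pax6 at 3.80 (8.30 to 12.10). Of the Hox genes of groups 1 to 6, 11 of 17 were at least 2-fold higher, and of the retinoic acid response genes 4 of 7 were higher and 1 lower, with the retinoic acid receptor gene Rarb at 4.81 and Hoxb4 at 3.85. There are no replicates on either side, so these are values without a test.

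Of 16 pluripotency genes, 12 were at least 2-fold lower in the rosette and 10 of them at least 4-fold, with a list median of -2.76. The list of epiblast and primitive streak genes had 10 of 14 members at least 2-fold lower, 1, Lhx1, higher by 1.95, and a median of -2.72, with Lefty2 at -4.63, Lefty1 at -4.18, Pim2 at -4.06 and Eomes at -3.64. Fgf5, an epiblast growth factor, was lower by -3.27. Nodal and TGF-beta targets had a median of -2.97, and 4 of 7 were at least 2-fold lower, including Cer1 at -3.55 and Nodal itself at -2.97. The medians of these 3 lists lay below those of all 10000 random lists (percentile 0). Lefty1 and Lefty2 also count among the Nodal and TGF-beta targets, so the lists are not separate results. The random lists were drawn gene by gene and do not carry the correlation of genes regulated together, so extreme percentiles are easier to reach. FGF and ERK feedback genes were also at percentile 0, with a median of -0.95, and 9 of 18 were at least 2-fold lower while 2, Dusp4 and Ccnd1, were higher. The ETS factor Etv5 stood at -3.52, Etv1 at -2.13 and the ERK inhibitor Spry4 at -1.93.

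Neuroepithelial genes had a median of 1.35, and 9 of 15 were at least 2-fold higher, including Dach1 at 2.66, Fabp7 at 2.15 and Zbtb16 at 2.01. Sox1, an early neural factor, differed by 0.50, and 4 of the 15 were at least 4-fold higher. In the list of ventral neural tube and SHH response genes 7 of 12 were at least 2-fold higher, with a median of 1.04. The SHH target Hhip was higher by 2.65, and the ventral progenitor factors Nkx2-2, Nkx6-1 and Olig2 were higher by 1.77, 1.57 and 1.51. Dorsal neural tube genes had a median of -0.02 (percentile 88.2), although Pax3 was higher by 1.96. Hox genes of paralog groups 1 to 6 had a median of 1.79, with 11 of 17 at least 2-fold higher and 8 of them at least 4-fold, including Hoxb5 at 3.75, Hoxa2 at 3.67 and Hoxb2 at 3.64. Hox genes of groups 7 to 13 had a median of -0.17 (percentile 33.6). The forebrain and midbrain list had a median of -0.13 (percentile 48.8), and its member Otx2, which EpiSCs also express, was at -2.46. Retinoic acid response genes had a median of 1.64, with 4 of 7 at least 2-fold higher, among them Crabp2 at 3.49, and 1 lower, the retinoic acid degrading enzyme gene Cyp26a1 at -1.01. The neuroepithelial, Hox 1 to 6 and retinoic acid medians were at percentile 100, and the ventral median was at 99.99.

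Markers of neurons, a cell type beyond the rosette stage, were higher too. Of 18 neuronal genes, 14 were at least 2-fold and 12 at least 4-fold higher (median 2.73, percentile 100), with Elavl4 at 4.44, Syt1 at 4.17, Nefm at 3.69 and Tubb3 at 2.98. Of 11 motor neuron genes, 4 were at least 2-fold higher (median 0.87, percentile 99.99), with Tbx20 at 3.13 and Slit2 at 2.68. OPC markers had a median of -0.02 (percentile 48.9), with Ptprz1 at 3.25 and Olig1 at -0.03. Mki67, a proliferation marker, differed by 0.10, and the median of the cell cycle genes was -0.25 (percentile 0.14), with 0 of 37 at least 2-fold apart.

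In all, 507 genes were at least 4-fold apart, 348 higher and 159 lower in the rosette, and 2113 were at least 2-fold apart. The largest increases, besides those above, were in Ednrb (4.49), Neurod4 (4.48), Nhlh1 (4.43), Rtn1 (4.41), Scg3 (4.37), Chrna3 (4.32), Lin7a (4.28) and Glra1 (4.22). The largest decreases included the hormone precursor gene Trh (-6.03), Ap1s3 (-4.40), Cldn6 (-4.15), Phlda2 (-4.14) and Epcam (-4.10). The 95th percentile of the absolute difference over genes was 1.52 here, against 0.49 between the OPC arrays and 0.91 between the oligodendrocyte arrays.

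**Figure D2:**
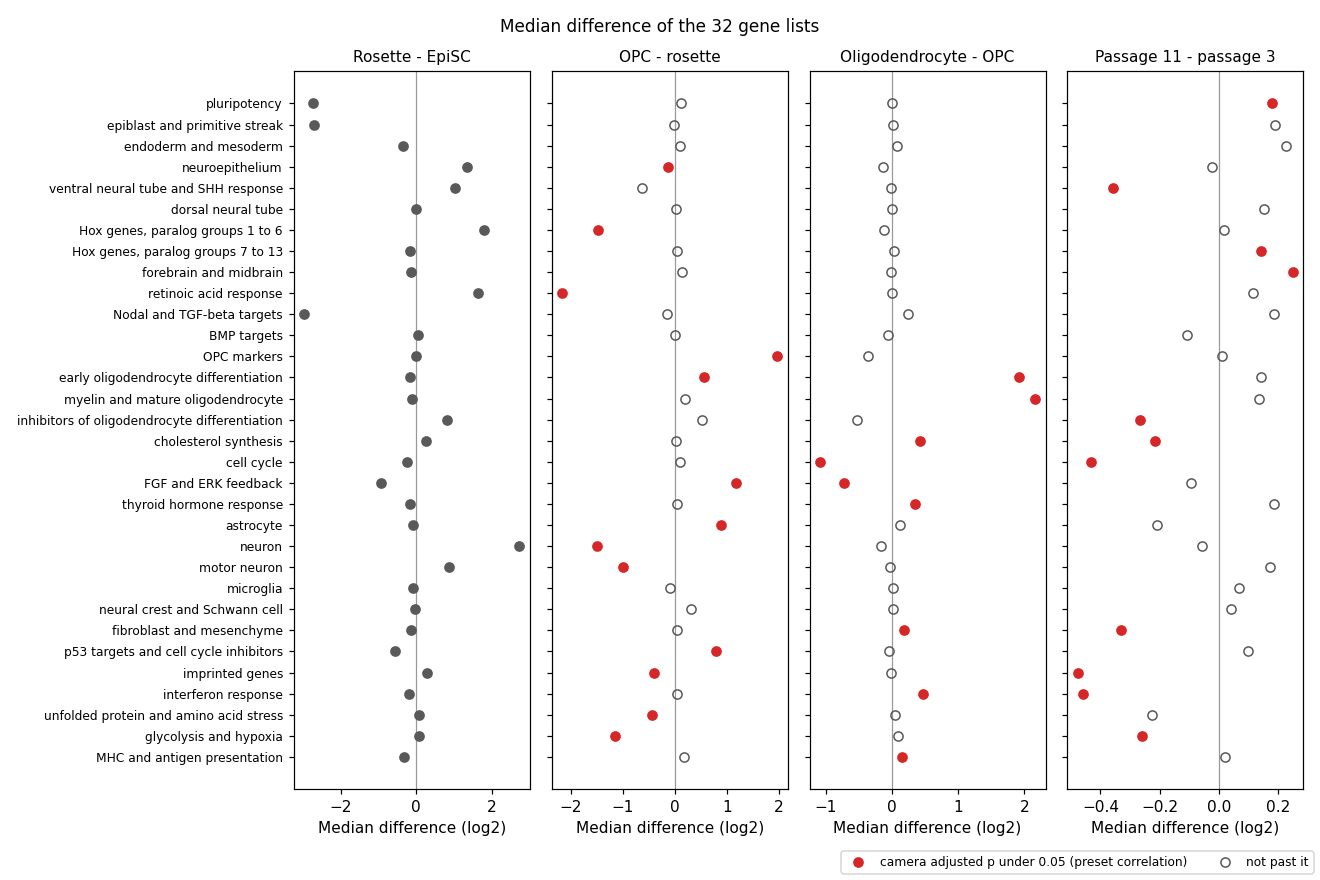
Median difference (log2) of each of the 32 gene lists in the 4 comparisons, 1 point per list, with red points where camera passed an adjusted p of 0.05 at its preset correlation open points where it did not, and filled grey points where no test was made. The scale differs between panels, and the passage medians, from -0.48 to 0.25, are the smallest.

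The second comparison asked how OPCs differ from the rosettes they were derived from. OPC genes rose strongly: the oligodendrocyte lineage factor Olig1 by 5.01 ± 0.28 (32.1-fold, adjusted p = 0.0058) and the PDGF receptor gene Pdgfra by 4.62 ± 0.29 (24.6-fold, adjusted p = 0.0058), each from 2 OPC arrays and 1 rosette array. The spread of the rosette was not measured, so every p-value of this comparison borrows that of the OPC and oligodendrocyte pairs. Olig2, already present in the rosette, rose by 3.39 ± 0.22 (adjusted p = 0.0058), and Sox10, a regulator of the lineage, by 1.97 (adjusted p = 0.0104). Retinoic acid targets and neuronal genes went the other way, with the retinoic acid binding protein gene Crabp2 at -5.19 ± 0.23, Rarb at -4.95 ± 0.19 and the neurofilament genes Nefl at -4.54 ± 0.32 and Nefm at -3.87 ± 0.17. The neuroepithelial factor Pax6 fell by 2.70 (SE 0.22, adjusted p = 0.0085).

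Of 24 OPC markers, 15 rose and 0 fell over all genes tested, and 18 rose adjusted over the list alone, with a median of 1.96. Beside Olig1 and Pdgfra these included the proteoglycan gene Bcan at 3.85 ± 0.23 and Omg at 3.60 ± 0.26. Ptprz1 rose by 3.22 and Cspg4, which encodes NG2, by 1.95. Camera gave this list an adjusted p of 9.46e-22 (adjusted p = 0.143 with an estimated correlation). FGF and ERK feedback genes had a median of 1.18, with 8 of 18 rising and 1, the phosphatase gene Dusp4, falling (10 and 1 adjusted over the list alone). Etv5 rose by 3.97 ± 0.17, Etv1 by 3.29 ± 0.23, Spry4 by 3.19 ± 0.34 and Spry2 by 2.68 ± 0.17, and camera gave the list an adjusted p of 8.14e-09 (adjusted p = 0.329 with an estimated correlation). Markers of astrocytes, another glial type, moved with the OPC genes. Of 16 astrocyte genes 5 rose and 0 fell (6 and 1 adjusted over the list alone), with a median of 0.89, led by Slc4a4 at 3.04 ± 0.25, Acsbg1 at 2.88 ± 0.29, Aldoc at 2.80 ± 0.31 and Mlc1 at 2.51 ± 0.35, and with Slc1a3 at 1.60. Its camera adjusted p was 2.81e-05 (adjusted p = 0.261 with an estimated correlation).

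Hox genes of paralog groups 1 to 6 had a median of -1.48; 8 of 17 fell, and 13 fell adjusted over the list alone. Hoxb5 was at -3.39 ± 0.36, Hoxb4 at -2.76 ± 0.26, Hoxb1 at -2.43 ± 0.24 and Hoxb2 at -2.42 ± 0.32. Of 7 retinoic acid response genes 6 fell (7 adjusted over the list alone), with a median of -2.16, including Dhrs3 at -2.16 ± 0.27. Camera gave these 2 lists adjusted p of 1.76e-12 and 3.36e-12 (adjusted p = 0.143 for each with an estimated correlation). Neuronal genes had a median of -1.50, and 7 of 18 fell (11 adjusted over the list alone), with a camera adjusted p of 7.71e-11 (adjusted p = 0.143 with an estimated correlation). Tubb3 was at -2.78 ± 0.48 and did not pass (adjusted p = 0.0537, and 0.0383 with passage as a block). Of 11 motor neuron genes 3 fell, namely Slc18a3 at -2.21, Isl1 at -2.11 and Neurog2 at -1.78 (5 adjusted over the list alone), with a list median of -0.99 and a camera adjusted p of 3.70e-06 (adjusted p = 0.353 with an estimated correlation). Fry gave the OPC, Hox 1 to 6, retinoic acid and neuronal lists an adjusted p of 0.0086 each, and the other 9 lists called by camera here had fry adjusted p from 0.0681 to 0.256. No list passed by the directional fry test in oligodendrocytes against OPCs (lowest adjusted p = 0.0635, for myelin genes) or between passages (lowest adjusted p = 0.122, for glycolysis). The mixed fry test, which ignores direction, did pass lists in oligodendrocytes against OPCs, with myelin genes at an adjusted p of 0.0157. Between passages the mixed test passed none (lowest adjusted p = 0.174).

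Glycolysis and hypoxia genes were lower in OPCs, with a median of -1.15, and 5 of 14 fell (9 adjusted over the list alone). The pyruvate dehydrogenase kinase gene Pdk1 was at -3.34 ± 0.19, Bnip3 at -3.26 ± 0.22 and the glucose transporter gene Slc2a1 at -2.63 ± 0.30, with Vegfa at -1.63 and Pfkl at -1.62 as the others that fell, and camera gave an adjusted p of 9.83e-09 (adjusted p = 0.329 with an estimated correlation). Of 15 neuroepithelial genes 5 fell and 0 rose over all genes (6 and 1 adjusted over the list alone), namely Pax6, Dach1 at -2.49 ± 0.21, Prom1 at -2.03 ± 0.19, Zbtb16 at -1.59 and Msi1 at -1.32, with a median of -0.13, a mean of -0.68 and a camera adjusted p of 0.0088 (adjusted p = 0.329 with an estimated correlation, and 0.0577 without dim genes; median -0.22 without OPC replicate 1). Ventral neural tube and SHH response genes had a median of -0.64 and were not called (adjusted p = 0.0974, and 0.0459 with passage as a block). Their median was -1.07 without OPC replicate 1 and -0.31 without OPC replicate 2. In that list Olig2 rose and Foxa1 fell by 1.60, while Nkx2-2 was at 1.21 ± 0.42 (adjusted p = 0.256, and 0.0470 with passage as a block) and Nkx6-1 at -0.80 (adjusted p = 0.569). Without OPC replicate 1 Nkx6-1 was at -1.26, and without OPC replicate 2 at -0.34. The list of early oligodendrocyte differentiation had a median of 0.56, and 1 of 13 rose, the receptor gene Gpr17 at 1.54 (6 rose and 1 fell adjusted over the list alone), with a camera adjusted p of 0.0038 (adjusted p = 0.353 with an estimated correlation). Myelin genes had a median of 0.20 (adjusted p = 0.0765, 0.0488 with passage as a block, 0.0448 without OPC replicate 2 and 0.0421 without either oligodendrocyte replicate), and of 33 members 1 rose, Gjc3 at 4.13 ± 0.61, and 1 fell, Nfasc at -1.28 ± 0.17 (5 and 2 adjusted over the list alone), while Cnp was at 1.19 (adjusted p = 0.127).

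In all, 624 genes were called, 251 higher and 373 lower in OPCs, and 3067 had an unadjusted p under 0.05, against 996.9 by chance. Further named increases were Gabrg1 (4.88), Scrg1 (4.59), Timp4 (4.54), Kcnma1 (4.31), Neto1 (4.16), Kcnip3 (3.89) and Slc6a11 (3.87). Further decreases were Chrna3 (-4.91), Glra1 (-4.53), Neurod4 (-4.38), Nhlh1 (-4.26), Mdk (-4.12), Mab21l2 (-3.79), Prmt8 (-3.66) and Serping1 (-3.62). With passage as a block 1206 genes were called. The count was 208 without OPC replicate 1, 156 without OPC replicate 2, and 2897 without either oligodendrocyte replicate. All 624 genes kept their direction without either OPC replicate, while the oligodendrocyte arrays enter only the spread and not the difference. These genes were chosen on the same arrays, so a kept direction followed largely from that choice.

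The third comparison asked what changes when OPCs become oligodendrocytes. Myelin genes rose: Mag, a myelin membrane glycoprotein gene, by 5.24 ± 0.13 (37.8-fold, adjusted p = 0.0018), Mbp, for myelin basic protein, by 3.91 ± 0.20 (15.0-fold, adjusted p = 0.0153), and Mog by 3.83 ± 0.26 (14.2-fold, adjusted p = 0.0247), each from 2 arrays a group. Enpp6, a marker of newly formed oligodendrocytes, had the largest increase among the called genes named, 5.33 ± 0.47 (40.3-fold, adjusted p = 0.0407), and Myrf, the transcription factor that drives myelin genes, rose by 2.59 ± 0.20 (adjusted p = 0.0294). Cell cycle genes were lower as a group, with 37 of 37 negative and a median of -1.08, although 0 of 37 fell over all genes tested and the list's camera call was lost with an estimated correlation (adjusted p = 0.770). OPC markers as a group were not called by camera (median -0.36, adjusted p = 0.423), with Pdgfra at -0.61 (adjusted p = 0.387) and Cspg4 at -0.80 (adjusted p = 0.192). Without oligodendrocyte replicate 1 Pdgfra was at -0.92, and without replicate 2 at -0.30. Over all genes tested 0 of the 24 fell and 2 rose, Tnr by 2.08 (adjusted p = 0.0298) and Gpr17 by 1.97 (adjusted p = 0.0407). Adjusted over the list alone, 3 rose and 2 fell, and 15 of the 24 were negative.

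Of 33 myelin and mature oligodendrocyte genes, 19 rose and 0 fell over all genes tested, and 29 rose adjusted over the list alone. Their median was 2.16, 2.03 at passage 3 and 2.09 at passage 11, with a camera adjusted p of 1.58e-38 (adjusted p = 0.477 with an estimated correlation). Besides the genes above, the tight junction gene Cldn11 rose by 3.90 ± 0.23, Tmem88b by 3.88 ± 0.18, Mobp by 3.65 ± 0.19, the fatty acid hydroxylase gene Fa2h by 3.16 ± 0.17 and Cnp by 2.68. The list of early oligodendrocyte differentiation had a median of 1.91, and 4 of 13 rose (10 adjusted over the list alone), namely Enpp6, Myrf, Gpr17 and Tmem163 at 3.21 ± 0.27, with a camera adjusted p of 4.30e-11 (adjusted p = 0.477 with an estimated correlation). Its member Bmp4 was at 2.55 ± 0.71 and did not pass (adjusted p = 0.255).

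Of 37 cell cycle genes, 0 fell over all genes tested in limma and 35 fell adjusted over the list alone. Bub1 was at -1.48 ± 0.49, Kif23 at -1.48 ± 0.51, Cenpe at -1.47 ± 0.42 and Mki67 at -1.44 ± 0.46 (-0.84 at passage 3 and -2.03 at passage 11). The list median was -0.75 at passage 3 and -1.38 at passage 11, and camera gave the list an adjusted p of 5.32e-24 (adjusted p = 0.770 with an estimated correlation). FGF and ERK feedback genes had a median of -0.73, and 7 of 18 fell adjusted over the list alone, 0 over all genes, including Spry4 at -1.46 ± 0.28, Spry1 at -1.33 ± 0.19 and Etv4 at -1.14 ± 0.19, with a camera adjusted p of 8.93e-07 (adjusted p = 0.770 with an estimated correlation). Thyroid hormone response genes had a median of 0.34, and 3 of 6 rose adjusted over the list alone, 0 over all genes, with Hr at 1.48 ± 0.24 and Klf9 at 1.09 ± 0.14 and a camera adjusted p of 0.0081 (adjusted p = 0.770 with an estimated correlation, and 0.0575 without oligodendrocyte replicate 2). All 19 cholesterol synthesis genes were positive, with a median of 0.43 (0.04 at passage 3 and 0.76 at passage 11), 2 rising adjusted over the list alone, and a camera adjusted p of 1.99e-06 (adjusted p = 0.770 with an estimated correlation, and 0.0880 without OPC replicate 2). Ebp was at 0.99 ± 0.18 and Hmgcs1 at 0.46 (0.12 at passage 3 and 0.80 at passage 11). Without oligodendrocyte replicate 2 the medians were -0.67 for cell cycle, -0.45 for FGF and ERK feedback and 0.20 for thyroid hormone response, and Mki67 was at -0.73. The thyroid median was 0.54 without oligodendrocyte replicate 1, and the cholesterol median was 0.66 without OPC replicate 1 and 0.22 without OPC replicate 2.

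Camera also called the interferon, fibroblast and MHC lists higher, although 0 of their members rose over all genes tested. The interferon list had a median of 0.48, 1.01 at passage 3 and 0.07 at passage 11, with Ifit3 at 1.73 ± 0.61 and Cxcl10 at 1.63 ± 0.99 (camera adjusted p = 0.0191; adjusted p = 0.770 with an estimated correlation). The fibroblast and mesenchyme list had a median of 0.18, 0.64 at passage 3 and 0.08 at passage 11, with Dcn at 1.44 ± 0.41 and Tagln at 1.33 ± 1.28 (camera adjusted p = 0.0444; adjusted p = 0.770 with an estimated correlation). The MHC and antigen presentation list had a median of 0.16, 0.38 at passage 3 and 0.12 at passage 11 (camera adjusted p = 0.0191; adjusted p = 0.770 with an estimated correlation). Without oligodendrocyte replicate 1 none of these 3 lists was called, with adjusted p of 0.800, 0.884 and 0.220 in that order. The fibroblast list was also not called without OPC replicate 2 (adjusted p = 0.159), nor the MHC list without OPC replicate 1 (adjusted p = 0.0898). Without oligodendrocyte replicate 2 their medians were 1.05, 0.86 and 0.30, and all 3 were called. None of the 3 was called without dim genes, with adjusted p of 0.0722, 0.122 and 0.412 in the same order, nor the fibroblast list after a second quantile normalization (0.0526) or centring (0.0525). Without dim genes the medians were 0.66 for interferon, 0.32 for fibroblast and 0.06 for MHC genes. Astrocyte genes had a median of 0.12, -0.13 at passage 3 and 0.49 at passage 11 (adjusted p = 0.637, and 0.0398 without OPC replicate 1), with S100b at 2.70 ± 0.58 and Gfap at 1.49 ± 0.57, neither past the threshold. Gfap was at 0.58 without oligodendrocyte replicate 1 and at 2.39 without replicate 2. With 1 oligodendrocyte array left, the spread comes from the OPC pair alone. For Gfap the SD was 2.05e-05 in OPCs and 1.28 in oligodendrocytes. P-values of such fits therefore do not measure variation between oligodendrocyte cultures. Hox genes of groups 1 to 6 had a median of -0.12 (adjusted p = 0.0813, and 0.0396 with passage as a block).

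In all, 89 genes were called, 79 higher and 10 lower in oligodendrocytes, and 2458 had an unadjusted p under 0.05, against 996.9 by chance. Other increases were Rasgef1b (4.43), Elovl7 (3.48) and Tppp (3.23), and outside the myelin genes Tnr, Gpr17, the TGF-beta inhibitor Smad7 (1.79) and Bnip3 (1.69; adjusted p = 0.0441, and 0.0531 with passage as a block). The decreases were Sting1 (-2.14), Moxd1 (-2.06), Grm5 (-1.70), Itga8 (-1.57), Lgr5 (-1.46), Slc29a1 (-1.45), Rps6ka6 (-1.38), Gap43 (-1.36), Fam72a (-1.36) and Chrm3 (-1.31). With passage as a block, 7 of these decreases no longer passed, Sting1, Itga8, Lgr5, Rps6ka6, Gap43, Fam72a and Chrm3, while Car3 (-2.71) and Cd93 (-1.99) did. At both passages 302 genes were at least 2-fold apart in the same direction, 228 higher and 74 lower.

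The count of 89 was 2 without OPC replicate 1, 4 without OPC replicate 2, 2919 without oligodendrocyte replicate 1 and 1365 without oligodendrocyte replicate 2, with the direction of all 89 genes kept in these 4 fits. Mag and Cldn11 were the genes called without OPC replicate 1, and with them Tmem88b and Mobp without OPC replicate 2. The 89 genes were chosen on the same arrays, so a kept direction followed largely from that choice. The direction split of 79 and 10 became 43 and 0 after a second quantile normalization and 17 and 0 after centring of each array on its median, so the 10 decreases passed in neither. Without dim genes it was 20 and 0, without oligodendrocyte replicate 1 it was 1151 higher and 1768 lower, and without oligodendrocyte replicate 2 it was 1004 and 361.

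**Figure D3:**
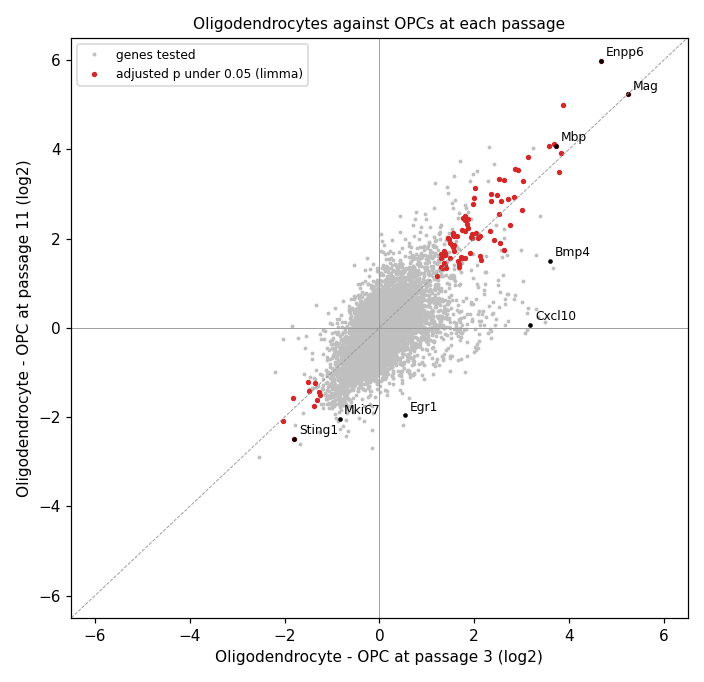
Oligodendrocyte minus OPC difference (log2) of each gene at passage 3 (x axis) and at passage 11 (y axis), with genes called by limma in red and named examples labelled in black. Mag and Mbp lie high at both passages, and the differences correlated across genes at 0.602.

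The fourth comparison asked whether passage 11 cells differ from passage 3 cells in OPCs and oligodendrocytes. Cdh19, a cadherin gene of neural crest and glial cells, was higher at passage 11 by 3.32 ± 0.11 (9.97-fold), with the same difference of 3.32 in each cell type. Lower at passage 11 were Stmn2, a neuronal gene, at -3.55 ± 0.45, Plp2 at -3.54 ± 0.15, and the matrix genes Thbs2 at -3.21 ± 0.22 and Nid1 at -2.74 ± 0.19. No gene passed the test: limma called 0 genes, with 2769 at an unadjusted p under 0.05 against 996.9 by chance, and the smallest adjusted p was 0.0928, for Cdh19. Myelin genes (median 0.14, adjusted p = 0.0853) and OPC markers (median 0.01, adjusted p = 0.881) were not called by camera.

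Cell cycle genes had the strongest list result, with 36 of 37 lower at passage 11 and a median of -0.43, -0.14 in OPCs and -0.81 in oligodendrocytes (camera adjusted p = 9.96e-10; adjusted p = 0.663 with an estimated correlation). Ccnb2 was at -1.10 ± 0.28 and Mki67 at -0.81 ± 0.31. Fibroblast and mesenchyme genes had a median of -0.33, -0.01 in OPCs and -0.92 in oligodendrocytes (camera adjusted p = 0.0046; adjusted p = 0.663 with an estimated correlation), with Tagln at -2.73 ± 0.56 and Acta2 at -1.54 ± 0.22. Interferon genes had a median of -0.46, 0.00 in OPCs and -0.85 in oligodendrocytes (camera adjusted p = 0.0287; adjusted p = 0.663 with an estimated correlation). Imprinted genes had a median of -0.48, -0.07 in OPCs and -0.84 in oligodendrocytes, with Peg10 at -1.09 ± 0.42 and Grb10 at -0.82 ± 0.11, and glycolysis and hypoxia genes one of -0.26, with Egln3 at -1.33 ± 0.20 (camera adjusted p = 0.0043 for each; adjusted p = 0.663 with an estimated correlation). Ventral neural tube and SHH response genes had a median of -0.36, -0.52 in OPCs and -0.09 in oligodendrocytes, with Shh at -1.07 ± 0.27 and Nkx6-1 at -0.86 ± 0.11 (camera adjusted p = 0.0126; adjusted p = 0.663 with an estimated correlation).

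Inhibitors of oligodendrocyte differentiation had a median of -0.26, 0.00 in OPCs and -0.34 in oligodendrocytes, with Hes1 at -0.87 ± 0.28 and Notch1 at -0.85 ± 0.13 (camera adjusted p = 0.0224; adjusted p = 0.663 with an estimated correlation). Cholesterol synthesis genes had a median of -0.22, but -0.49 in OPCs and 0.16 in oligodendrocytes (camera adjusted p = 0.0308; adjusted p = 0.746 with an estimated correlation). With the intensity trend between passages removed, neither of these 2 lists was called (adjusted p = 0.106 for each). The 3 lists called higher hold mostly dim genes, with median levels of 7.96, 8.46 and 8.24, all below the median of all values: Hox groups 7 to 13 (median 0.14, camera adjusted p = 0.0224), forebrain and midbrain (0.25, 0.0258) and pluripotency (0.18, 0.0314), each with an adjusted p = 0.663 with an estimated correlation. After removal of the same trend, none of these 3 was called, nor after a second quantile normalization (adjusted p = 0.133, 0.0578 and 0.133). Without dim genes the calls of the ventral, interferon, inhibitor, cholesterol, Hox 7 to 13 and forebrain lists were lost (adjusted p from 0.138 to 0.294), and centring ended that of cholesterol synthesis (0.0522). The medians without dim genes were -0.36 for ventral, -0.26 for inhibitor, -0.22 for cholesterol and 0.15 for Hox 7 to 13 genes. They were -1.04 for interferon and 0.17 for forebrain genes, and centring gave -0.26 for cholesterol. Cdkn2a, a senescence-associated cell cycle inhibitor gene, was at 0.31 ± 0.11 (adjusted p = 0.359).

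By size, 79 genes were at least 2-fold apart in the same direction in both cell types, 12 higher and 67 lower at passage 11. The other named higher genes were Hepacam (1.76), Neurod1 (1.52), Nptx1 (1.48), Lipf (1.45), Pcdh10 (1.43), Pstpip2 (1.38), Plppr5 (1.31), Rftn2 (1.27), Gabrg1 (1.17) and S100a16 (1.07). The other lower genes were Anxa3 (-3.04), Crym (-2.87), Apela (-2.51), Cav1 (-2.44), Myof (-2.40), Mme (-2.38) and Sulf1 (-2.32). The passages were at least 2-fold apart in 125 genes in OPCs and in 785 in oligodendrocytes, where 154 were higher and 631 lower at passage 11.

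**Figure D4:**
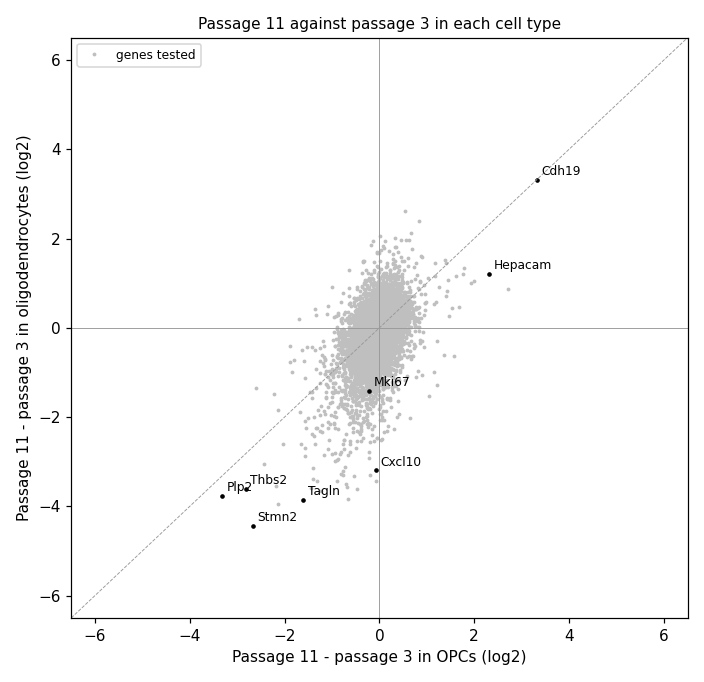
Passage 11 minus passage 3 difference (log2) of each gene in OPCs (x axis) and in oligodendrocytes (y axis), with named examples labelled in black and the dashed line at equality. Cdh19 lies at 3.32 in both, and the spread is wider in oligodendrocytes.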

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

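All tests of explanations given here were chosen after the results they concern had been seen, and the differences between passages or cell types listed here were not tested. A gene or list is given where its difference went opposite ways in the 2 passages or cell types by at least 0.49 for genes and 0.1 for list medians. For oligodendrocytes minus OPCs, Ddx58, an RNA sensor gene of the interferon response, was at 1.40 at passage 3 and -0.50 at passage 11. The early response genes Egr1 and Egr2 were at 0.54 and 0.64 at passage 3 and at -1.96 and -0.57 at passage 11. Tbx20, a motor neuron factor, was at 0.53 and -0.59. The list medians at passages 3 and 11 were -0.21 and 0.13 for ventral neural tube and SHH response, -0.13 and 0.49 for astrocyte, 0.19 and -0.38 for p53 targets and cell cycle inhibitors, and 0.19 and -0.19 for imprinted genes. For passage 11 minus passage 3, the medians in OPCs and oligodendrocytes were -0.49 and 0.16 for cholesterol synthesis and 0.36 and -0.16 for p53 targets and cell cycle inhibitors. With all transcripts of the table tested in OPCs against the rosette, 18 of the 227 called transcripts had no symbol or several symbols and belong to no named gene.

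Some contractile, interferon and astrocyte genes stood higher on the oligodendrocyte array of passage 3 than on that of passage 11, with Tagln at 13.34 against 9.49, Cxcl10 at 11.16 against 7.97 and Gfap at 10.50 against 8.69. The astrocyte list as a whole was not called between passages (camera adjusted p = 0.0777). Its passage median was -0.17 in OPCs and -0.19 in oligodendrocytes, and its median over OPCs was -0.13 at passage 3 and 0.49 at passage 11. An intensity trend left by the normalization is argued against by its size. Its medians over bins of intensity lay between -0.14 and 0.14 in oligodendrocytes. In the fibroblast, interferon and astrocyte lists, 13 members were at least 2-fold lower at passage 11 in oligodendrocytes. Their median was -1.93 before and -1.89 after the trend was removed. The members were chosen for that drop, so these medians show little beyond the small size of the trend. RNA from fibroblasts in the passage 3 culture remains a possible explanation that cannot be told apart from a response of the cells themselves, since 7 of the 13 fibroblast list members already stood above the median of all values in OPCs at passage 3, 1 is on another list, and no cell sort is named in the labels. The 6 collagen and proteoglycan genes that fibroblasts express most had a median difference from OPCs of 0.22 at passage 3, but they split, with Dcn at 1.57 and Col1a1 (level 10.10 against 9.82 in OPCs) at 0.28, Col1a2 at 0.28, Col3a1 at 0.01, Col6a3 at 0.00 and Lum at 0.17, against a median of 0.98 for Acta2, Tagln and Thbs2. Tagln and Thbs2 were at least 2-fold lower at passage 11 in OPCs too, so for them the drop was not confined to oligodendrocytes. By list median the drop was in oligodendrocytes, with fibroblast genes at -0.92 against -0.01 in OPCs. Interferon genes were at -0.85 against -0.0023. Passage itself stays open as a biological explanation, untested, since each passage has 1 oligodendrocyte array.

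The oligodendrocyte arrays were at least 2-fold apart in 785 genes and the OPC arrays in 125. The measured intensity trend was too small to account for this either. After its removal, which moved 10205 genes by over 0.1 in oligodendrocytes, 774 and 131 genes were that far apart. A larger share of differentiated cells at passage 11 may be involved: of the genes at least 2-fold apart from OPCs at both passages, 68.9% of the higher (157 of 228) and 71.6% of the lower (53 of 74) had the larger difference at passage 11. Both shares lie between the bounds set for the test, so the share of differentiated cells cannot be told apart from another difference between these 2 cultures. The myelin list median over OPCs was nearly the same, 2.03 at passage 3 and 2.09 at passage 11. Among its members Mag was at 5.25 and 5.23, while Mog was at 3.57 and 4.08. Passage, which the design names, stays open and untested.

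The 3 lists called higher at passage 11, pluripotency, Hox groups 7 to 13 and forebrain and midbrain, hold mostly dim genes. An intensity trend left by the normalization between passages is a candidate explanation: after its removal 0 of the 3 lists was still called. The median of pluripotency went from 0.18 to 0.07 (adjusted p = 0.244), that of Hox groups 7 to 13 from 0.14 to 0.03 (adjusted p = 0.264) and that of forebrain and midbrain from 0.25 to 0.16 (adjusted p = 0.0871). Of the 8 lists called lower, 6 were still called, and inhibitors of oligodendrocyte differentiation and cholesterol synthesis were not (adjusted p = 0.106 for each). A biological difference by passage stays open and was not tested apart from the trend.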

How the results depend on the processing

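Removal of the intensity trend between passages, and every alternative for the genes 2-fold apart between passages in both cell types, were chosen after the data had been seen; the others were planned. All 89 genes called between oligodendrocytes and OPCs kept their direction in the 4 fits that left out 1 replicate each, and all 624 called between OPCs and the rosette kept theirs without either OPC replicate. The oligodendrocyte arrays do not enter that difference. Both sets were chosen on these same arrays, so a kept direction followed largely from the choice and is not independent support. Over the 4 fits the numbers called ranged from 2 to 2919 and from 156 to 2897. The fits leave 1 residual degree of freedom and assume that the lone array varies like the other group, so the spread comes from the OPC pair alone or from the more variable oligodendrocyte pair alone. Among named genes called in the main or the reduced fit, the only reversal was Ddx58 in oligodendrocytes against OPCs, which ranged from -0.72 without oligodendrocyte replicate 1 to 1.62 without oligodendrocyte replicate 2. Uncalled genes with small differences also changed sign, such as Nkx6-1 in that comparison, at -0.16 with all replicates and 0.30 without OPC replicate 1. Lists called only with a replicate left out were, for OPCs against the rosette, inhibitors of oligodendrocyte differentiation (adjusted p = 0.0117 without OPC replicate 2, 0.0176 without either oligodendrocyte replicate) and cholesterol synthesis (0.0025 without OPC replicate 2). For oligodendrocytes against OPCs they were astrocyte genes (0.0398), p53 targets (0.0053) and glycolysis (0.0013) without OPC replicate 1, inhibitors (0.0228) without oligodendrocyte replicate 1, and imprinted genes (0.0010) and glycolysis (9.47e-04) without oligodendrocyte replicate 2.

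For oligodendrocytes against OPCs the 89 calls became 43 after a second quantile normalization, 17 after centring on the array median, 20 without dim genes, 1 with all transcripts and 208 at an adjusted p of 0.10. For OPCs against the rosette the 624 calls became 227 with all transcripts and 1157 at that threshold. Between passages the 0 calls became 1 with a variance trend in limma and 1 at the threshold of 0.10. The looser threshold adds calls by construction; otherwise the cause was not tested. Lists called between passages went from 11 to 7 without dim genes (6 lost, and epiblast and myelin gained with adjusted p of 0.0442 and 0.0190), 8 after quantile normalization, 10 after centring and 6 with the intensity trend removed. Epiblast and pluripotency genes can pass the dim filter through the EpiSC array alone. Their list medians were 10.90 and 11.58 there, but lay between 8.13 and 8.45 on the OPC and oligodendrocyte arrays. Between oligodendrocytes and OPCs the 9 became 6 without dim genes and 8 after either normalization, and between OPCs and the rosette the 13 became 12 without dim genes. With an estimated correlation 0 lists were called in each comparison, against 13, 9 and 11. In the simulation that setting called a list shifted by 1 in 0 of 3 runs of each comparison. A call lost under it therefore cannot tell a changed list from an unchanged one.

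Of the counts by size, the 507 genes 4-fold apart between rosette and EpiSCs became 817 with all transcripts and 2113 at 2-fold. The 302 genes 2-fold apart from OPCs at both passages became 41 at 4-fold, 634 at passage 3 alone and 1003 at passage 11 alone. The 79 genes apart between passages became 158 with all transcripts, 125 in OPCs alone and 785 in oligodendrocytes alone. These changes follow from the rules themselves.

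With passage as a block, which uses the pairing of OPCs and oligodendrocytes, 1206 genes were called between OPCs and the rosette, 621 of them among the 624. Between oligodendrocytes and OPCs the block called 83, of which 58 were among the 89; the cause was not tested. Low signals limit all of these counts, since background cannot be told from expression here.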

Other observations

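Lists not described so far also differed between stages. OPCs had higher p53 targets and cell cycle inhibitors than the rosette (median 0.79, camera adjusted p = 7.17e-05; adjusted p = 0.535 with an estimated correlation), and 1 of 14 rose, the CDK inhibitor gene Cdkn2c at 1.89. The same list was lower in the rosette than in EpiSCs, with a median of -0.57 (percentile 0) and Perp at -3.08. Imprinted genes were lower in OPCs (median -0.39, camera adjusted p = 1.56e-04; adjusted p = 0.535 with an estimated correlation), and 1 of 18 fell, Cdkn1c, by 2.01. Genes of the unfolded protein and amino acid stress response were lower in OPCs too (median -0.44, camera adjusted p = 0.0012; adjusted p = 0.329 with an estimated correlation), and 1 of 12 fell, Atf3, by 1.01. BMP targets had a median of 0.00 in OPCs against the rosette (adjusted p = 0.984). Within the list Id3 rose by 1.46, while Id4 was at -1.66 and was not called (limma adjusted p = 0.0265 with passage as a block). Adjusted over the list alone, 1 rose and 1 fell. In the rosette against EpiSCs the median was 0.05, with Id2 at 2.55 and Id4 at 2.07.

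Camera called none of the lists of microglia, endoderm and mesoderm, or neural crest and Schwann cells in the 3 tested comparisons, and the rosette against EpiSCs was not tested. Microglia genes had medians of -0.10 in the rosette against EpiSCs, -0.10 in OPCs against the rosette (adjusted p = 0.347), 0.02 in oligodendrocytes against OPCs (adjusted p = 0.757) and 0.07 between passages (adjusted p = 0.267). Endoderm and mesoderm genes had medians of -0.35 in the rosette against EpiSCs (percentile 0.83) and 0.11 in OPCs against the rosette (adjusted p = 0.333). Neural crest and Schwann cell genes had a median of 0.32 in OPCs against the rosette (adjusted p = 0.984), where 2 of 10 fell, the neurotrophin receptor gene Ngfr by 1.81 and Tfap2b by 1.25.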
